A study of Gallus gallus with 9 samples.

How the data were processed

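RNA abundance was measured in the amacrine cell layer of the chick retina on Affymetrix Chicken Genome arrays, on which each gene is read by 1 or more probe sets of short oligonucleotides placed towards the 3' end of its transcripts. Per the labels' protocols, chicks wore a lens of -7 D or 7 D over 1 eye for 24 h or stayed untreated, under 12 h of light a day at 500 lux. The layer was cut by laser capture from sections 10 µm thick, total RNA was purified with a micro-column kit, and 10 to 100 ng of it went through 2 rounds of amplification before hybridisation. The labels describe 3 chicks and 3 separately prepared samples for each condition, which gives 9 arrays in 3 groups of 3. They do not say which sample came from which chick. The source label of the minus lens arrays names both lenses, so their group was taken from the sample titles.

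The authors deposited 1 intensity for each probe set and array, on a linear scale, and the submitters' processing notes name GCRMA, with its version not given in the sources used here. GCRMA corrects background from the base composition of the probes, normalises arrays to a common distribution and summarises the probes of a set. That the scale was linear was read from the values, whose highest entry was 57319 to 68331 on the 9 arrays and whose median was 7.57 to 8.32. GCRMA pulls dim probe sets towards a narrow floor, so differences there are small whatever the RNA did. The normalisation also removes any change in total RNA, so each difference is relative to the other transcripts on the array.

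Log2 was taken of the deposited intensity with no pseudocount. Of 38535 probe sets, 96 control probe sets and 746 others of non-chicken or reporter sequences were left out of the tests. Of the 37693 chicken probe sets, 12975 (34.4%) reached log2 4 on at least 3 of the 9 arrays and were tested. Gene symbols came from the platform annotation: 9978 tested probe sets had 1 symbol, 47 had several and 2950 had none, and no gene was named from the last 2 kinds. Of the chicken probe sets with 1 symbol, 26851 were found by Entrez number in the RefSeq gene table of the GRCg7b assembly, which changed 0 symbols. No coordinates are given, since that table's build is not tied to the array.

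Differences between group means were tested in limma 3.58.1 under R 4.3.3 (lmFit, then eBayes with an intensity trend) with all 9 arrays in 1 fit, two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05 on the adjusted p. The fit had 6 residual and 2.64 prior degrees of freedom. An F test asked whether any of the 3 groups differed. Of 34 gene lists written down for this tissue and treatment, 25 had at least 5 measured genes and were tested with limma's camera at its preset correlation of 0.01, adjusted over the 25 lists. The lists covered amacrine transmitters, immediate early genes, growth and patterning pathways, receptors, energy and protein metabolism, stress and markers of other cell types. Each gene was read from its probe set with the highest mean over the 9 arrays, giving 7130 genes, and 10 list members were matched through a synonym of a listed symbol, some of them a related gene rather than the gene listed. Camera asks whether the genes of a list lie higher or lower than the other genes. Because the preset correlation is low for genes that vary together, each call is given beside its adjusted p with the correlation estimated from these arrays. The 2 settings can also differ for a list whose estimated correlation is close to 0.01. A call lost with an estimated correlation therefore does not by itself show that the genes vary together.

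The groups, tests, gene lists, most alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, up to 12 genes in each direction past the threshold with groups that did not overlap, filled to 5 by smallest p where fewer passed, and up to 4 members of each list discussed. EGR1, GCG, VIP, BMP2, TH, CHAT, PENK, SST, FOS and PER2 were to be given whatever their values. Genes of lists without a shift are named where they passed over the list alone.

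The code was tested on simulated data built from the real arrays for the minus lens against control comparison. Of 200 probe sets among 12975 changed by log2 1, 58.4% were recovered, with 5.47% false calls among those called. At log2 2 the share was 95.6%, and at log2 0.5 it was 0%. A list of 35 genes shifted by log2 0.3 among 7130 genes was found in 10 of 10 runs. The simulated noise was independent between genes, whereas the genes of that list had an estimated correlation of 0.233 on the real arrays. The runs therefore do not show how the list test behaves where genes vary together. For arrays there is no read depth, and the number of arrays limits the precision: the median standard error of a log2 difference was 0.19. No 2 arrays held identical values.

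Alternatives were other filters on dim probe sets, quantile normalisation or median centring of the deposited values, arrayWeights, eBayes without the trend or with robust fitting, the replicate number as a block, fits to the 6 arrays of a comparison, other thresholds, and each array left out in turn. For the lists they were also an estimated correlation and the mean of a gene's probe sets.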

Results

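Amacrine cells are interneurons of the inner retina, and in chicks they are among the cells studied for how the retina reads the sign of defocus and steers the growth of the eye. A minus lens focuses images behind the retina and stimulates growth, and a plus lens focuses them in front and suppresses it. Gene expression in the captured amacrine cell layer was compared after 24 h between 3 minus lens, 3 plus lens and 3 untreated arrays. Each array had 12721 to 12835 chicken probe sets at log2 4 or above. P-values here measure the spread between these samples, which may be technical in part.

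The captured tissue had high signal for some amacrine cell genes and for some glial genes. Apart from PENK, CHAT and TH, the cell type genes named here fall outside the rule for naming genes. On the control arrays GAD1, an enzyme of GABA synthesis, stood at log2 14.26 ± 0.11 (SD, n = 3), the opioid peptide precursor PENK at 13.47 ± 0.12, the transcription factor PAX6 at 13.13 ± 0.02 and the calcium-binding CALB2 at 12.82 ± 0.15. The Müller glia genes GLUL (glutamine synthetase) and VIM (vimentin) stood at 13.56 ± 0.43 and 12.72 ± 0.12. Not all amacrine genes were bright: the acetylcholine enzyme gene CHAT stood at 5.31 ± 2.24, and the dopamine enzyme gene TH lay below the filter. Markers of other cell types were present too: 13 of 25 for Müller glia, 11 of 22 for ganglion cells and 10 of 21 for bipolar cells were measured above the filter, against 12 of 17 for amacrine GABA and glycine genes, 6 of 9 for acetylcholine, 13 of 23 for neuropeptides and 3 of 12 for dopamine. Of the photoreceptor markers 3 of 38 were measured, of the horizontal cell markers 4 of 12, of the microglial and leukocyte markers 3 of 24, of the endothelial and pericyte markers 3 of 19 and of the red blood cell markers 1 of 20. A marker not measured lay below the filter or had no probe set with its symbol. These shares therefore do not by themselves tell which cells were captured. Minus lens replicate 3 stood apart from the other arrays. Its mean correlation with them was 0.953, against 0.971 to 0.975 for the others, its hybridisation controls stood at log2 13.17 against 11.53 to 12.19, and arrayWeights gave it a weight of 0.3004. The gaps between 3' and 5' control probe sets, which widen as RNA degrades or amplification falls short, did not separate any 2 groups for actin, elongation factor 1 or GAPDH. Their exact permutation p ran from 0.2 to 1 (0.833 to 1 after Benjamini-Hochberg adjustment), where 3 against 3 arrays can give no less than 0.1.

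Minus lens wear went with lower signal of 1 uncharacterised gene and with shifts of 5 gene lists at the preset correlation, where an estimated correlation gave 0 lists (smallest adjusted p = 0.153). LOC425969 fell to log2 4.10 ± 0.23 (SD, n = 3) from 6.07 ± 0.15 in controls, a 3.91-fold difference (log2 -1.97, SE 0.18, adjusted p = 0.0285). It was the 1 probe set of 12975 that passed in limma. At an unadjusted p under 0.05 there were 912 probe sets (380 higher, 532 lower), where chance gives 649. Other splits of the same 6 arrays, with the plus lens arrays kept in the fit, gave up to 1152. The call was lost without any 1 of the 3 controls (adjusted p = 0.186 to 0.244), without plus lens replicate 1 or 3 (0.0938 and 0.0950), without minus lens replicate 2 or 3 (0.0547 and 0.0736), after median centring (0.0607), with no filter on dim probe sets (0.0944) and with only the 6 arrays compared (0.117). Over the settings that tested it, which leave out the filter at log2 6, its adjusted p ran from 0.0154 to 0.244 and its log2 difference from -2.08 to -1.84.

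The genes next in order of p did not pass. Higher on all 3 minus lens arrays than on all 3 controls were GFRA1, a co-receptor for glial cell line-derived neurotrophic factor (log2 1.81, SE 0.24, adjusted p = 0.166), GNG13, a G protein subunit of bipolar and taste cells (1.39, SE 0.16, adjusted p = 0.122), VSX1, a homeobox gene of bipolar cells (0.96, SE 0.14, adjusted p = 0.275), the haem-binding SOUL (1.15, adjusted p = 0.452) and NEB, which encodes the muscle protein nebulin (2.47, adjusted p = 0.361). The NEB controls averaged log2 3.24, below the filter, so the size of its difference is uncertain. Other NEB probe sets did not share that difference, with log2 0.52 for the brightest. Lower were SLC7A2, a transporter of cationic amino acids (-2.54, SE 0.37, adjusted p = 0.275), NFAT5, a transcription factor of the osmotic response (-2.15, adjusted p = 0.294, with a minus lens mean of log2 2.33, below the filter, so the size is uncertain), the immune receptor CD180 (-1.97, adjusted p = 0.516) and the AMPA receptor subunit GRIA3 (-1.08, adjusted p = 0.516), whose brightest probe set differed by -0.46. Arrays of the groups did not overlap for 563 probe sets upward and 736 downward, 10.0% of those tested, where chance gives 10%.

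Ribosomal protein genes, which encode the structural proteins of the ribosome, lay higher in the minus lens group. Of 62 measured, 57 had a higher mean than in controls, 23 without overlap of the arrays, and the median log2 difference was 0.34. None passed over all genes, and 22 passed adjusted over the list alone, all upward, among them RPS24 (0.79, SE 0.15), RPS15 (0.66), RPL37A (0.59) and RPL22 (0.49). A second, dimmer RPS24 probe set differed by -0.50. The list test gave an adjusted p of 1.07e-22, and adjusted p = 0.439 with an estimated correlation, with 2.40e-30 to 0.439 over all settings. The list mean was 0.46, 0.39 and 0.12 above the control mean on minus lens replicates 1, 2 and 3 and -0.07, 0.19 and -0.12 on the controls, so whole arrays overlapped.

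Genes of oxidative phosphorylation, the respiratory chain of mitochondria, also lay higher (60 genes, 49 of them upward, median 0.16, adjusted p = 2.40e-05). With an estimated correlation the adjusted p was 0.656, and over all settings it ran from 4.42e-10 to 0.656. None of the 60 passed over all genes and 0 adjusted over the list alone. The largest leads were NDUFA4 (0.53, SE 0.19, adjusted p = 0.683) and UQCRHL (0.45, SE 0.15, adjusted p = 0.683), followed by NDUFV2 (0.36) and NDUFB3 (0.31). A dimmer NDUFB3 probe set differed by -0.56. The median of this list moved with single arrays: it was 0.10 without control replicate 3, 0.10 without minus lens replicate 1, 0.07 without minus lens replicate 2 and 0.27 without minus lens replicate 3, and 0.25 with arrayWeights.

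Markers of bipolar cells, which lie next to the amacrine cells, lay higher as well (10 genes, 7 upward, median 0.24, adjusted p = 2.48e-04). With an estimated correlation the adjusted p was 0.153, with a range of 1.54e-04 to 0.282 over all settings. That correlation was 0.0125, close to the preset 0.01, while the unadjusted p of camera went from 2.97e-05 to 0.00610. The loss of this call can therefore not be put down to variation that the genes share. GNG13, VSX1 and OTX2 (0.90, SE 0.21, adjusted p = 0.617 over all genes) passed adjusted over the list alone, and 0 of the 10 passed over all genes. The kainate receptor gene GRIK1 had a log2 difference of 0.81 (SE 0.33) and did not pass, and its second probe set differed by -0.34. The list mean was 0.52, 0.30 and 0.38 on the 3 minus lens arrays and -0.05, -0.03 and 0.08 on the controls. Without the filter on dim probe sets the median was 0.09. Beside these, markers of Müller glia (median -0.13, adjusted p = 0.810) and ganglion cells (median 0.02, adjusted p = 0.932) did not pass. Lists too short to test had medians of 0.46 for photoreceptors (3 genes, of which GNB3, also a bipolar cell gene, passed over the list alone) and 0.30 for retinal pigment epithelium (4 genes), and the amacrine lists of GABA and glycine and of neuropeptides had -0.12 and -0.17, neither passing, and -0.03 and -0.05 without minus lens replicate 3.

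Heat shock genes, which encode chaperones that fold proteins, lay lower (19 genes, 14 downward, median -0.38, adjusted p = 6.71e-04, and adjusted p = 0.656 with an estimated correlation). HSPA8, an abundant chaperone, stood at 11.97 ± 0.46 against 12.99 ± 0.11 in controls and passed adjusted over the list alone, as 1 of the 19, while 0 passed over all genes. DNAJA1 (-1.43, SE 0.64), HSP90AA1 (-0.77, SE 0.32) and HSPA4L (-0.72, SE 0.26) did not pass, and a second HSPA4L probe set differed by -0.01. The decline sat on 2 arrays: the list mean was 0.06, -0.46 and -0.80 on minus lens replicates 1, 2 and 3. The median was -0.12 without minus lens replicate 3, the array that stood apart, and -0.56 without replicate 1, and the adjusted p ran from 4.56e-08 to 0.656 over all settings.

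Immediate early genes, which neurons switch on within minutes of activity, lay lower (12 genes, 10 downward, median -0.27, adjusted p = 0.00956, and adjusted p = 0.544 with an estimated correlation). None passed over all genes and 0 adjusted over the list alone. The leading members were DUSP4 (-0.81, SE 0.29), EGR1 (-0.74, SE 0.29), BTG2 (-0.52, SE 0.23) and NR4A2 (-0.38, SE 0.15), with adjusted p of 0.683 to 0.713 over all genes. The call was lost without control replicate 2 (adjusted p = 0.0644) or minus lens replicate 2 (0.0884), against 0.00313 to 0.544 over all settings. The median was -0.17 without minus lens replicate 3 and -0.10 without the filter on dim probe sets.

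**Figure D1:**
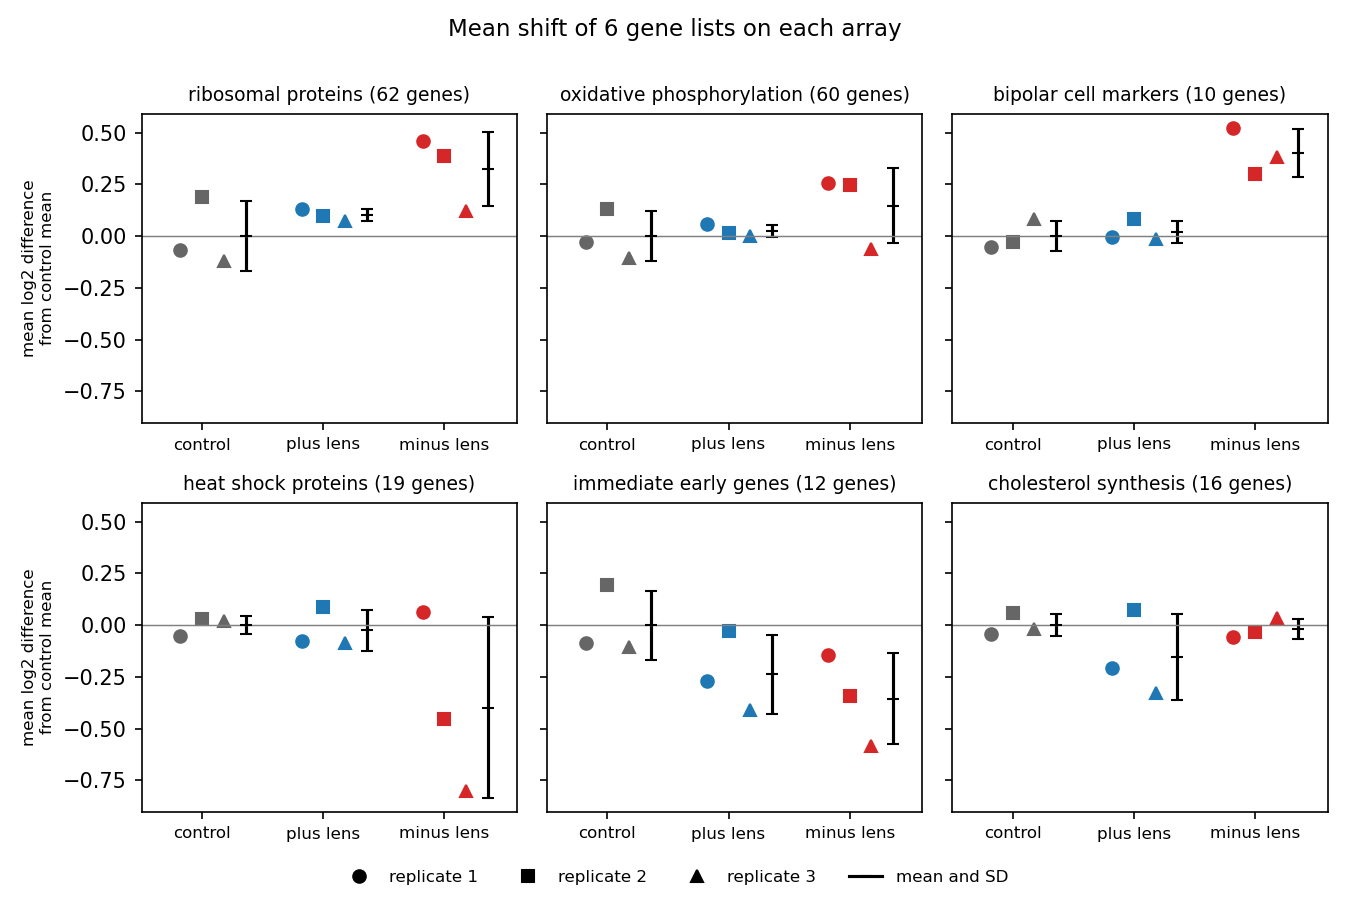
Mean log2 difference from the control mean, on the y axis, of 6 gene lists on each of the 9 arrays, with points for arrays and bars for the mean and SD of each group of 3. The ribosomal protein list stands at 0.46, 0.39 and 0.12 on the minus lens arrays and overlaps the controls, and the bipolar cell list stands at 0.52, 0.30 and 0.38 above all 3 controls.

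Plus lens wear went with higher signal of 1 gene, ODF2L, and with small shifts of 3 gene lists at the preset correlation, where an estimated correlation gave 0 lists (smallest adjusted p = 0.848). ODF2L, a relative of a protein of centrosomes and sperm tails, rose to log2 5.98 ± 0.18 (SD, n = 3) from 4.14 ± 0.04 in controls, a 3.56-fold difference (log2 1.83, SE 0.14, adjusted p = 0.00815). It was the 1 probe set of 12975 that passed in limma, and 253 had an unadjusted p under 0.05 (112 higher, 141 lower), fewer than the 649 of chance. Arrays did not overlap for 409 probe sets upward and 457 downward (6.67%, where chance gives 10%). The ODF2L call was lost without any 1 control (adjusted p = 0.0882 to 0.102), without plus lens replicate 3 (0.0683) and with only the 6 arrays compared (0.0546), within a range of 0.00206 to 0.102 over the settings that tested it, which leave out the filter at log2 6. On the control and minus lens arrays ODF2L lay close to the floor of the filter, at log2 4.04 to 4.42.

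LOC425969 had a log2 difference of -1.61 (SE 0.18, adjusted p = 0.0705) and GFRA1 of 1.92 (SE 0.24, adjusted p = 0.108), and neither passed among the probe sets. In the fit to 7130 genes with 1 probe set each, used for the lists, 3 genes passed: ODF2L (adjusted p = 0.00348), LOC425969 (0.0304) and GFRA1 (0.0434). The same fit gave 1 gene for minus lens against control (LOC425969, adjusted p = 0.0116) and 1 for minus lens against plus lens (ODF2L, 0.00493). Among the other genes by order of p, none of which passed, NEB had a difference of 2.95 (adjusted p = 0.194) from controls below the filter, with -1.07 at its brightest probe set. NSMCE3, a part of a complex that maintains chromosome structure, had 0.94, and KLF11, a zinc finger repressor, had 0.92 (adjusted p = 0.653) with -0.13 at a brighter probe set. Lower were UBE2N, a ubiquitin-conjugating enzyme (-2.51, SE 0.54, with -0.17 at its brightest probe set), and PRRC2C (-0.85, with -0.05 at its brightest). NCBP3 had -0.84 to a plus lens mean of log2 3.97, below the filter, with -0.20 at its brightest. CUL3 had -0.75, with 0.08 at a brighter one. The adjusted p was 0.9998 for each of these lower genes. Several differed alike under the minus lens against the same controls: NSMCE3 had 1.04, CUL3 -0.77, PRRC2C -0.68 and NCBP3 -0.60. KLF11 had -0.68 there and UBE2N -0.37.

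The ribosomal protein list lay higher under the plus lens too, by less (62 genes, 49 upward, median 0.10, adjusted p = 0.00252, and adjusted p = 0.848 with an estimated correlation). None passed over all genes and 0 adjusted over the list alone. Leading members were RPL22L1 (0.68, SE 0.33), RPS26 (0.37, SE 0.19), RPS24 (0.30, SE 0.15) and RPS7 (0.19, SE 0.11). A dimmer RPL22L1 probe set differed by -0.77 and another by 0.75. The list mean was 0.13, 0.10 and 0.08 on the plus lens arrays and -0.07, 0.19 and -0.12 on the controls. Control replicate 2 thus stood above every plus lens array. The call was lost without control replicate 3 (median 0.03, adjusted p = 0.857) or plus lens replicate 1 (adjusted p = 0.1001), and the median was 0.18 without control replicate 2, within adjusted p of 1.42e-10 to 0.857 over all settings.

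Immediate early genes lay lower (12 genes, 9 downward, median -0.21, adjusted p = 0.0199, and adjusted p = 0.848 with an estimated correlation). EGR1 stood at 7.42 ± 0.48 against 8.47 ± 0.41 in controls (log2 -1.05, SE 0.29, adjusted p = 0.9998), followed by DUSP4 (-0.85, SE 0.29), BTG2 (-0.33) and DUSP6 (-0.26). None passed over all genes and 0 adjusted over the list alone. The call was lost without control replicate 2 (median -0.12, adjusted p = 0.153), plus lens replicate 1 (adjusted p = 0.1001) or plus lens replicate 3 (median -0.10, adjusted p = 0.572) and without the filter on dim probe sets (median -0.09, adjusted p = 0.250). Over all settings the adjusted p ran from 0.00112 to 0.848.

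Genes of cholesterol synthesis lay lower (16 genes, 12 downward, median -0.18, adjusted p = 0.0199, and adjusted p = 0.848 with an estimated correlation). The leading members were FDPS (-0.50, to a plus lens mean of log2 3.92, below the filter), INSIG1 (-0.32, SE 0.17), SC5D (-0.27) and ACAT2 (-0.18), with 0 passing over all genes and 0 adjusted over the list alone. The list mean was -0.21, 0.07 and -0.33 on the 3 plus lens arrays. The call was lost without control replicate 2 (adjusted p = 0.118), plus lens replicate 1 (0.1001) or plus lens replicate 3 (median -0.10, adjusted p = 0.747), within 1.01e-04 to 0.848 over all settings. Beside these lists, markers of Müller glia had a median of -0.15 with 11 of 13 lower (adjusted p = 0.0616). Ganglion cell markers had -0.12 with 9 of 11 lower (adjusted p = 0.153) and bipolar markers a median of 0.02 (adjusted p = 0.981).

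The direct comparison of the lenses, which asks whether the sign of defocus changed expression, gave 2 probe sets, both lower under the minus lens. ODF2L stood at 4.22 ± 0.19 against 5.98 ± 0.18 under the plus lens (log2 -1.76, SE 0.14, adjusted p = 0.0114). KLF11 fell to 5.02 ± 0.16 from 6.62 ± 0.09 (log2 -1.60, SE 0.15, adjusted p = 0.0246), with controls between them at 5.70 ± 0.22. A brighter KLF11 probe set differed by -0.25, the same direction at a smaller size. The ODF2L call was lost without control replicate 2 or 3 (adjusted p = 0.0570 and 0.0577), without any 1 plus lens array (0.0561 to 0.0911), without minus lens replicate 1 (0.0641), after median centring (0.0539), with the replicate block (0.0828) and with only the 6 arrays compared (0.174), within 0.00414 to 0.174 over the settings that tested it. The KLF11 call was lost in each fit without 1 array except that without control replicate 1, after quantile normalisation (0.0772) or median centring (0.0739), with the replicate block (0.0828), with no filter on dim probe sets (0.0664) or the filter at log2 6 (0.158) and with only the 6 arrays compared (0.174), within 0.0160 to 0.186 over all settings.

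At an unadjusted p under 0.05 there were 918 probe sets (392 higher, 526 lower), where chance gives 649, and arrays did not overlap for 588 upward and 668 downward (9.68%, where chance gives 10%). Higher under the minus lens, and not passing, were PRTFDC1 (log2 1.53, with -0.34 at another probe set), GNG13 (0.94, SE 0.16), VSX1 (0.86, SE 0.14), FBXO22 (0.67, with 0.16 and -0.49 at other probe sets) and BEND7 (0.56), at adjusted p of 0.506 to 0.615. Lower were NFAT5 (-2.17, from the same minus lens mean below the filter), the hedgehog receptor PTCH1 (-0.62, SE 0.10) and CBWD1 (-0.60), at adjusted p of 0.494 to 0.506.

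**Figure D2:**
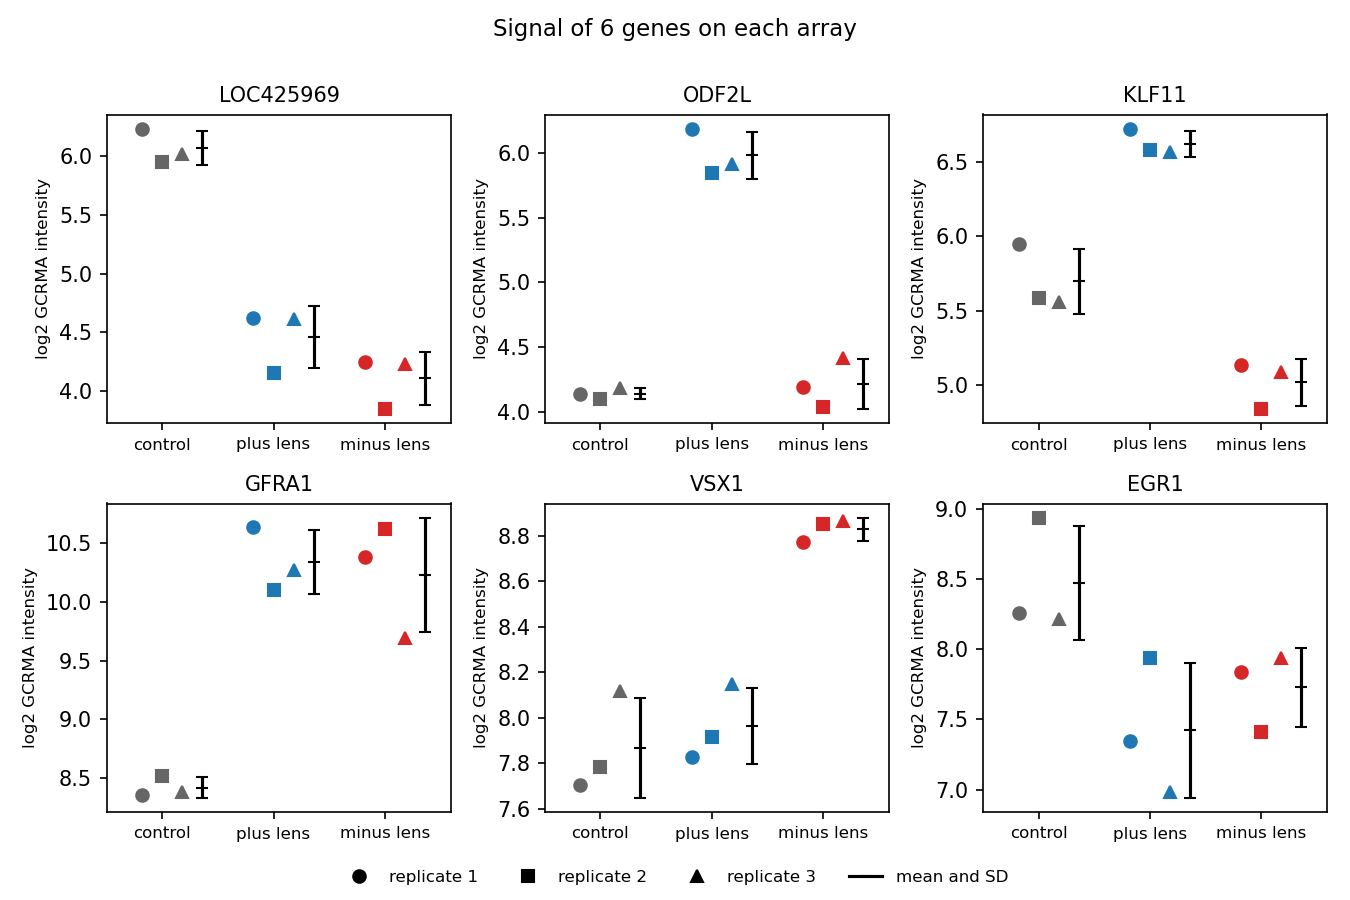
Log2 signal, on the y axis, of 6 genes on each of the 9 arrays, with points for arrays and bars for the mean and SD of each group of 3. LOC425969 stands at 6.07 in controls and 4.10 under the minus lens, and ODF2L stands at 5.98 under the plus lens against 4.14 in controls.

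Of the gene lists, 4 differed between the lenses. Ribosomal protein genes lay higher under the minus lens (56 of 62 upward, median 0.26, adjusted p = 2.11e-13, and adjusted p = 0.687 with an estimated correlation), with RPS16 at 0.65, RPS15 at 0.61, RPS24 at 0.49 and RPL27 at 0.42, where dimmer probe sets of RPS24 and RPL27 differed by -0.54 and -0.31. The median was 0.17 without minus lens replicate 1, and the adjusted p ran from 4.53e-16 to 0.687 over all settings. Bipolar cell markers lay higher (9 of 10 upward, median 0.20, adjusted p = 1.58e-05, and adjusted p = 0.0750 with an estimated correlation of 0.0125). GNG13, VSX1 and OTX2 (0.83, SE 0.21) passed adjusted over the list alone, and GRIK1 (0.71, SE 0.33, with -0.45 at its second probe set) did not. The bipolar median was 0.13 with the mean of each gene's probe sets, and the adjusted p ran from 8.83e-06 to 0.367 over all settings. Markers of Müller glia and ganglion cells had medians of 0.13 and 0.15 (adjusted p = 0.334 each). Without minus lens replicate 3 their medians were 0.22 and 0.25, neither passing, beside 0.23 for bipolar markers.

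Genes of oxidative phosphorylation lay higher under the minus lens than under the plus lens (45 of 60 upward, median 0.13, adjusted p = 3.48e-04, and adjusted p = 0.687 with an estimated correlation), with NDUFA4 at 0.49, NDUFA12 at 0.42, NDUFB3 at 0.41 (with -0.70 at a dimmer probe set) and UQCR11 at 0.39. Their median was 0.05 without minus lens replicate 1 or 2, 0.24 without replicate 3 and 0.21 with arrayWeights, and the adjusted p ran from 2.41e-08 to 0.687 over all settings. Heat shock genes lay lower (16 of 19 downward, median -0.36, adjusted p = 0.00111, and adjusted p = 0.687 with an estimated correlation), with DNAJA1 at -1.66, HSP90AA1 at -0.70, HSPA4L at -0.68 (with 0.30 at a second probe set) and HSPA8 at -0.65. That call was lost without minus lens replicate 2 (adjusted p = 0.0620), and the median was -0.55 without replicate 1 and -0.13 without replicate 3, within 6.47e-08 to 0.802 over all settings. In the ribosomal, respiratory and heat shock lists 0 genes passed over all genes and 0 adjusted over the list alone.

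The other 20 tested lists did not pass under the minus lens against control. Of the amacrine transmitter lists, genes of GABA and glycine had a median of -0.12 (adjusted p = 0.231), acetylcholine -0.06 (0.877) and neuropeptides -0.17 (0.522). Signalling lists gave a median of 0.01 for BMP and TGF-beta (adjusted p = 0.522), 0.20 for retinoic acid (0.127), -0.04 for WNT (0.460), -0.09 for insulin, IGF, FGF and EGF ligands and receptors (0.210) and -0.08 for the circadian clock (0.277). Receptor and synapse lists gave -0.05 for glutamate receptors (adjusted p = 0.107), -0.02 for GABA and glycine receptors (0.522), 0.05 for acetylcholine receptors (0.733), -0.12 for synaptic vesicle release (0.127) and -0.14 for voltage-gated channels (0.533). Glycolysis (-0.11, adjusted p = 0.345), cholesterol synthesis (0.00, 0.996), the unfolded protein response (-0.13, 0.231), the proteasome (0.00, 0.231) and extracellular matrix (0.04, 0.345) did not pass either. Several of these values rest on minus lens replicate 3, the array that stood apart. Without it the proteasome median was 0.14 and passed (adjusted p = 0.0178, and 0.00528 against the plus lens). The list of insulin, IGF, FGF and EGF passed in that fit too (median -0.08, adjusted p = 0.0311). There the medians of synaptic vesicle release, glycolysis and the unfolded protein response were -0.04, 0.03 and -0.04. Acetylcholine receptors and BMP and TGF-beta changed sign, to -0.10 and -0.05. Voltage-gated channels had -0.07, GABA and glycine genes -0.03 and neuropeptides -0.05. The median, the mean and the test of a list differed in sign in 13 combinations of list and comparison, 0 of them past the threshold.

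The 9 lists with under 5 measured genes were not tested. Their medians under the minus lens against control were 0.46 for photoreceptors, -0.08 for horizontal cells, 0.10 for oligodendrocytes, 0.30 for retinal pigment epithelium, 0.11 for red blood cells, 0.17 for microglia and leukocytes, 0.15 for endothelium and pericytes, -0.28 for dopamine and 0.02 for apolipoproteins and crystallins. These rest on 1 to 4 genes each. Some also moved with minus lens replicate 3. Without it the medians were -0.19 for oligodendrocytes, 0.40 for microglia and leukocytes and 0.07 for endothelium and pericytes. They were 0.20 for red blood cells, 0.20 for retinal pigment epithelium and -0.18 for dopamine.

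Several genes were followed because of their place in amacrine cells or in eye growth. EGR1, an activity marker of glucagon amacrine cells, had a log2 difference of 0.30 between minus and plus lens (SE 0.29, adjusted p = 0.813). The glucagon gene GCG had -0.92 under the minus lens and -0.21 under the plus lens against control (SE 0.28, adjusted p = 0.683 and 0.9998), and its second probe set -0.85 and 0.12. The peptide gene VIP had -0.82 and -0.51 (SE 0.40, adjusted p = 0.725 and 0.9998), PENK -0.17 and -0.01 (SE 0.10), the growth factor BMP2 0.01 and 0.33 (SE 0.33) and the clock gene PER2 0.15 and -0.15 (SE 0.19). CHAT, the acetylcholine-synthesising enzyme, had -0.62 and 0.87 with an SE of 1.18, since it stood at 2.73 on control replicate 1 and 2.50 on minus lens replicate 1 against 5.28 to 6.71 on the other arrays. The dopamine enzyme gene TH and FOS lay below the filter, and SST had 0 named probe sets. None of these passed in any comparison.

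Asked over the 3 groups together, 2 probe sets differed by the F test, and 686 had an unadjusted p under 0.05 where chance gives 649. The changes under the 2 lenses, each against the same controls, had a covariance of 0.0308 over 12975 probe sets. Unchanged groups simulated against 3 shared controls gave 0.0330 ± 0.0020 (SD, 100 simulations). The correlation across genes, which are not independent replicates, was 0.400 against a simulated 0.425 ± 0.019, and 61.5% of probe sets had the same sign against 64.2% simulated. Without 1 lens array, and with all 3 controls kept, the covariance ran from 0.0264 to 0.0372. It moved with single arrays by more than the simulated SD, which is therefore too narrow to judge the observed value by. The 3 controls are too few to split, and the covariance was 0.0484, 0.05003 and 0.0430 without control replicate 1, 2 or 3. With fewer shared controls chance also gives a higher covariance. That value was not simulated, so these cannot be set against 0.0330.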

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

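The lists under arrayWeights, without synonym matches and with an estimated correlation and no minus lens replicate 3, the written-out values of single lists, and the called genes under the filters, robust eBayes and the fits to 6 arrays, were chosen after the data were seen. Counts are given in the order minus lens against control, plus lens against control, minus lens against plus lens and, for probe sets, any group, set against 1, 1, 2 and 2 probe sets and 5, 3 and 4 lists. Where no reason is given, the cause was not tested.

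With no filter on dim probe sets there were 0, 1, 1 and 1 probe sets, and with the stricter filter at log2 6 there were 0, 0, 0 and 0, which leaves out LOC425969 and ODF2L and keeps KLF11, whose call it ended. Median centring, which raised minus lens replicate 3 by 0.13 and changed each other array by less than 0.1, gave 0, 2, 0 and 3, quantile normalisation 1, 1, 1 and 2, and arrayWeights 2, 3, 2 and 4. Fits to only the 6 arrays compared gave 0, 0 and 0, with fewer arrays to estimate the spread. An adjusted p under 0.10 gave 1, 2, 2 and 3, and an unadjusted p under 0.05 gave 912, 253, 918 and 686. Leaving out 1 array gave 0 to 4, 0 to 2, 0 to 2 and 0 to 2. Dropping the intensity trend, robust eBayes and a minimum log2 difference of 1 left the counts at 1, 1, 2 and 2, except for 3 in any group without the trend.

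With the replicate number as a block there were 1, 2, 0 and 0 probe sets and 5, 3 and 4 lists. Of the 9 pairs of arrays with the same number, 2 had deviations that correlated over 0.1 (range -0.06 to 0.16). Pairs with different numbers ran from -0.15 to 0.14. These values do not settle whether an equal number marks a shared preparation.

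With an estimated correlation 0, 0 and 0 lists passed, and 0, 0 and 0 also without minus lens replicate 3. Leaving out 1 array gave 4 to 7, 0 to 5 and 3 to 8 lists, and the other settings gave 5 to 7, 2 to 4 and 4 to 5. The covariance was 0.0132 with no filter, which brings in probe sets at the floor, and 0.0264 to 0.05003 without 1 array. The highest values came without a control, where chance also gives more. For 105 log2 differences of named genes, 1416 of 1470 alternative fits, each array left out among them, kept direction and call, 11 gained a call, 31 lost one, and 12 differed in sign with no call on either side. Most of these genes had no call to lose. For the 4 calls, with the settings added later, 38 of 69 fits lost the call: 10 of 17 for LOC425969, 5 of 17 and 9 of 17 for ODF2L against control and between the lenses, and 14 of 18 for KLF11. Signal close to the background limits these data: 34.4% of chicken probe sets passed the filter.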

Other observations

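The tests that leave out 1 array, that compare 3' with 5' probe sets and that weigh cell types were chosen or tightened after the results were seen, and the splits of 6 arrays were run in a second form after the first was seen. The genes of the next paragraph were chosen because they passed over their own list.

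Some genes passed adjusted over their own list although the list did not shift and none passed over all genes. Among 11 measured genes of retinoic acid handling, a pathway tied to eye growth, the degrading enzyme CYP26A1 had a log2 difference of -1.61 under the minus lens (SE 0.50, adjusted p = 0.683 over all genes) and -1.85 under the plus lens. The synthesising enzyme ALDH1A3 had -0.43 (SE 0.13) against control and -0.61 against the plus lens. The binding proteins CRABP1 and RBP4 had 0.44 (SE 0.14) and 1.49 (SE 0.51) under the minus lens. Under the plus lens they had 0.04 and 1.16. Of 13 glutamate receptor genes, GRIA3 (-0.46, SE 0.13), the NMDA receptor subunit GRIN2A (-0.98, SE 0.31) and the metabotropic receptor GRM8 (-0.43, SE 0.13) passed over the list alone, all lower on the 3 minus lens arrays than on the 3 controls.

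GNB3, a G protein subunit of cones and of ON bipolar cells, was 1 of 3 measured photoreceptor markers. It had 0.82 under the minus lens and 0.45 under the plus lens (SE 0.15), higher on all 3 arrays of each lens than on all 3 controls, with adjusted p of 0.495 and 0.9998 over all genes. ASNS, which makes asparagine and responds to amino acid shortage, had 0.98 between minus and plus lens (SE 0.22, adjusted p = 0.655 over all genes) and passed over the list of the unfolded protein response.

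Ribosomal protein genes lay higher under the minus lens. The values argue against minus lens replicate 3 alone, since the median was 0.34 with it and 0.454747 without it (adjusted p = 8.63e-25, against 2.40e-30 to 0.439 over all settings). Of 10000 lists matched on mean signal, 0 had a median as high, which argues against an error that depends on signal level. RNA quality stays open. The 3' minus 5' gap separated the groups for 0 of 3 control transcripts, yet its mean differed by 0.40 for elongation factor 1 and -0.17 for actin. The elongation factor gap was 6.12, 5.79 and 6.78 on minus lens replicates 1, 2 and 3. Its difference thus rests largely on replicate 3, where the ribosomal list mean was lowest of the group. Over all arrays and the 3 transcripts the gaps were wide, at log2 3.66 to 7.99. The lens may act on these genes, which was not tested apart from the comparison itself, and the loss of the call with an estimated correlation (0.357 between the genes of the list) leaves variation that these genes share, whatever its source, as another candidate.

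Bipolar cell markers lay higher under the minus lens. Without minus lens replicate 3 the median was 0.229509 (adjusted p = 0.00282, against 1.54e-04 to 0.282 over all settings), which argues against that array alone. A smaller share of amacrine cells in the captured tissue, made up evenly by other cells, would raise markers of all other cell types alike. A cut that took in more of 1 neighbouring cell type would not, and the gaps given here cannot exclude it. Against the controls the values argue against such an even replacement as the whole cause. The bipolar minus ganglion cell mean of the lowest minus lens array exceeded that of the highest control by 0.188213. This was more than the SD of 0.16 between minus lens arrays and of 0.17 between controls. For bipolar minus Müller glia the excess was 0.0686789, less than the SD of 0.33 between minus lens arrays, so that gap decides nothing by itself. Other values go with a smaller share in part. Without minus lens replicate 3, medians against the plus lens were alike: 0.23 for bipolar cells, 0.22 for Müller glia and 0.25 for ganglion cells. Against the controls that fit gave 0.23, -0.09 and 0.09. The bipolar minus ganglion mean also reached 0.30 on a plus lens array with no bipolar rise, against 0.31 on the lowest minus lens array. Its SD between plus lens arrays was 0.19, no smaller than the excess over the controls, so this gap does not decide either. Means of the short lists of photoreceptors, pigment epithelium, microglia and endothelium were 0.43, 0.37, 0.36 and 0.46 higher under the minus lens. Their control SDs were 0.32, 0.50, 0.46 and 1.20. Horizontal cells, oligodendrocytes and red blood cells had -0.08, 0.10 and 0.11, with control SDs of 0.14, 0.20 and 0.08. The photoreceptor mean was also 0.43 higher under the plus lens, where bipolar markers did not rise. A smaller share may therefore contribute, and the gaps do not settle by how much. More bipolar cells in the cut tissue stay open, as 4 of 10 markers were higher on all 3 minus lens arrays than on all 3 controls, where chance gives 5%. A response of bipolar genes to the lens was not tested apart from these.

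Immediate early genes lay lower under both lenses. The list mean was -0.14, -0.34 and -0.58 on the minus lens arrays and -0.27, -0.03 and -0.41 on the plus lens arrays. On the controls it was -0.09, 0.19 and -0.10, so plus lens replicate 2 stood above control replicates 1 and 3. Of 10000 lists matched on mean signal, at most 22 had a median as low in either comparison, which argues against an error that depends on signal level. Both calls of the list test were lost without control replicate 2, which both comparisons share. That array stays open as a source of the calls. Under the minus lens the median was -0.27 with it and -0.30 without it (adjusted p = 0.0644), so the call was lost but not the size. Under the plus lens it was -0.21 with that array and -0.12024 without (adjusted p = 0.153). Over all settings the adjusted p ran from 0.00313 to 0.544 and from 0.00112 to 0.848. Untreated chicks differ from both lens groups in handling and in wearing no lens, so an effect common to any lens may lie behind this and cannot be separated from defocus by these groups.

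Regrouping the arrays bears on the counts. Each number of splits below counts the real one. Over 100 splits of the 9 arrays into 3 groups, the real one and drawn ones, 21 gave at least the 2 probe sets of the real groups by the F test, with up to 5 in another split, so chance is not excluded for that count. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. With the other group kept in the fit, probe sets for minus lens against control numbered 1 in the real split and at most 2 in another, with 5 splits giving as many. For plus lens against control they numbered 1 and at most 1, with 4 splits, and for minus against plus lens 2 and at most 2, with 2 splits. At an unadjusted p under 0.05 the real splits gave 912, 253 and 918 probe sets, with 1152, 719 and 963 as the highest others. Lists numbered 5 against at most 4 in another split (1 split, the real one), 3 against at most 5 (5 splits) and 4 against at most 4 (3 splits). In the form run first, with only the 6 arrays in the fit, the real probe set counts were 0, 0 and 0, with 2, 0 and 2 as the highest others, and the lists numbered 5, 1 and 4, with 5, 5 and 6 as the highest others and 3, 8 and 4 splits giving as many. In that form the 5 lists under the minus lens were matched by another split.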
